A study of Danio rerio with 6 samples.

How the data were processed

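Total RNA from zebrafish (Danio rerio, TL strain) embryos was measured per the labels at 72 hours post fertilisation, after injection of a control, an AHRRa or an AHRRb morpholino at the first cleavage stages. A morpholino is an antisense oligonucleotide that blocks the translation or splicing of a transcript; the labels do not say which kind was used or how many embryos made up a sample. Each of 6 Agilent arrays, 2 per group, carried embryo RNA labelled with Cy5 and a universal reference RNA labelled with Cy3, with no dye swap.

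The scanner files were made with Agilent Feature Extraction 9.1.3.1 per the file headers, from images of a GenePix scanner at 5 micron per pixel. They hold, per the file headers, the mean intensity of each spot and the median intensity of its local background in both channels, processed intensity values after the software's own detrending and dye normalization, and a log10 ratio of Cy5 over Cy3. The deposited series table holds a log2 ratio for each of 21495 probes, made with Agilent Feature Extraction and limma per the labels, with no version or settings given. Its values were checked against the scanner files. Across probes the slope of the series table on the scanner's log10 ratio was between 3.25 and 3.72, and the median of each column lay between -0.01 and -0.00.

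The values reported come from the scanner files. Spot intensity was background corrected with normexp at an offset of 50 and normalized within each array by loess (span 0.3) in limma 3.58.1 under R 4.3.3. Control spots and spots marked as outliers had no weight in the loess curve, and control spots were left out of every test. The 42990 remaining spots were averaged over the 2 spots of each probe. A probe was tested when the scanner software called it well above background in Cy5 on both arrays of at least 1 group, which left 5006 probes with 4157 distinct names, of which 3225 were assigned gene symbols. Symbols came from the annotation of assembly GRCz12tu, by transcript accession for 9998 of the 21495 probes and by gene name or synonym for 1408, and the other 10089 kept the name in the files. That assembly is from the Tuebingen strain, and the probes were not aligned to it.

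A group-means model was fitted with limma to all 6 arrays, so that the 3 groups shared one estimate of the spread for each probe, with 3 residual and 4.71 prior degrees of freedom. Contrasts were AHRRa against control, AHRRb against control and AHRRa against AHRRb, and probes passed at a Benjamini-Hochberg adjusted p under 0.05. Changes are log2 differences of the Cy5 to Cy3 ratio between group means, followed by the standard error of the model, with 2 arrays against 2. Where a group had no array well above background for a gene, the fold is given as a bound: the mean Cy5 signal of the other group over the lowest Cy5 signal called well above background on each array of the dim group, or over the gene's own signal where that was higher. These bounds use Cy5 alone, so they are open to dye bias with no dye swap, and where one exceeded the fold of the Cy5 to Cy3 ratios no fold is given. Such a group is called dim for the gene. A bound is on the group means and takes no account of the spread between arrays.

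Gene lists for 28 tissues, cell types and pathways were written before the data were examined, as were the comparisons, the test, the alternatives and the rule for named genes. The 22 lists with at least 4 measured genes were tested with camera at a preset inter-gene correlation of 0.01, with 1 probe per gene (the one with the highest mean intensity) and adjustment over the lists of a comparison. A gene without a value on every array was left out of that test, which among list genes was mcm7 of the cell cycle list. The AHR pathway, cone, rod, retinal transcription factor, visual cycle, lens, globin, erythroid, neutrophil and macrophage, heart, skeletal muscle, liver, exocrine pancreas, epidermis, neuron, glia, cartilage, cell cycle, circadian, heat shock and hatching gland lists were tested, with 1 more that enters the counts and is not reported here. The blood stem cell and lymphoid list (3 measured), the endocrine pancreas and pituitary list (2), the intestine list (3), the pigment cell list (3), and the interferon and the vascular lists (0 each) were not. Camera with an estimated correlation and fry were run as alternatives.

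The genes named are the AHR pathway genes ahrra, ahrrb, ahr2, cyp1a, cyp1b1, cyp1c1 and cyp1c2 whatever their p. To these were added the 8 genes with the largest rise and the 8 with the largest fall past the threshold, with both arrays on one side of both control arrays and an assigned symbol, and up to 4 members of each list past the threshold. Where fewer than 8 passed, the next by p were given as values that did not pass. For AHRRa against AHRRb the number was 5 in each direction. Members named to complete a small count (opn1lw2, arr3b, gngt2a, six7, tbx2b, stra6, amy2a, fga, fgg, apoeb, fabp10a, cldnb, hbae3, hbbe2, ctrb.3, snap25b and sypb) were chosen after their values were seen.

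The labels give replicate numbers but no pairing, so no block was fitted. The file headers put both control arrays on one slide and scan and the 4 knockdown arrays on another, so a term for the slide could not be fitted for a comparison with control. Alternatives were the software's processed signals, no background correction, an offset of 10, median centring in place of loess, Aquantile and scale normalization between arrays, Cy5 alone with quantile normalization, no filter and a stricter filter on dim probes, the mean over the probes of a gene, the deposited series table, a model of only the 2 groups compared, eBayes with trend and robust, a replicate block, a threshold of 0.1, and each array left out in turn. Array weights were added after the data were seen.

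The pipeline was tested on simulated data with 200 of 5006 probes changed in each of 10 simulations. For AHRRa against control it recovered 9.55% of changes of 0.5 on the log2 scale, 81.4% of changes of 1 and 98.5% of changes of 2, and 4.88% of its calls were false. A shift of the cone list was called in 10 of 10 simulations with the preset correlation and in 8 with an estimated one, and 0 of 220 unshifted lists were called. Simulated genes varied independently and with one spread in all groups. In the data the lens list had an estimated correlation of 0.76, and replicates differed with a standard deviation of 0.42 in AHRRa against 0.18 in control. The simulated rates of false calls therefore do not carry over to the real lists and probes. Array number limits the precision, and median Cy5 signal was 1.13 to 1.22 times the local background.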

Results

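The experiment asked which transcripts change in zebrafish embryos when either of a pair of aryl hydrocarbon receptor repressor (AHRR) genes is knocked down. AHRR proteins bind the same partner as the aryl hydrocarbon receptor (AHR), the ligand-activated transcription factor that responds to dioxins, and repress its activity. RNA from embryos at 72 hours post fertilisation was hybridised to 2 arrays in each of 3 groups, injected with a control, an AHRRa or an AHRRb morpholino. The control arrays had 5444 and 4915 of 21495 probes well above background in Cy5, the sample channel. The AHRRa arrays had 2705 and 3496, and the AHRRb arrays had 4527 and 5180. Across tested probes, which are not independent replicates, the log2 ratios of replicate arrays correlated at r = 0.76 for control, 0.33 for AHRRa and 0.79 for AHRRb. The second AHRRa array correlated at 0.16 and 0.35 with the first and second control array, the latter slightly above its own replicate. For the first AHRRa array these values were 0.07 and -0.04. Both control arrays lay on one slide and all 4 knockdown arrays on another, so slide and knockdown cannot be told apart in a comparison with control. The labels do not say whether replicates were separate clutches or pools, so the p-values measure only the spread between these arrays.

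No probe matched either targeted gene, ahrra (chromosome 24, 46125519 to 46144061 in assembly GRCz12tu) or ahrrb (chromosome 2, 53501034 to 53566730), so the knockdown could not be checked on its own transcript. Neither did a probe match the AHR target genes cyp1b1, cyp1c1 and cyp1c2. The tested probe of ahr2, the main zebrafish receptor for dioxins, was dim on both AHRRa arrays, with a fitted log2 change of -0.01 ± 0.19 against control (adjusted p = 0.98) that is no bound on the fold and has a sign that turned under 4 alternatives, 2 of them leaving out the first control or the second AHRRa array. In AHRRb it had 0.32 ± 0.19 (adjusted p = 0.56). The probe of cyp1a, the classic AHR-induced cytochrome P450, was dim on both AHRRa arrays. Its bound on the group means was 1.46-fold lower, but the difference did not pass (adjusted p = 0.16). In AHRRb it had -0.85 ± 0.19 (adjusted p = 0.11), where 1 of 2 arrays was well above background. Of the 4 measured members of the AHR pathway list, 0 passed the test in either knockdown (0 in AHRRa and 1 in AHRRb adjusted over the list alone), and camera gave the list an adjusted p of 0.61 in AHRRa and 0.77 in AHRRb.

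AHRRa against control asked what loss of the first repressor changes, and its 8 largest falls were all in photoreceptor genes. The genes pde6ha (chromosome 6, 310434 to 312130) and pde6c had log2 changes of -3.25 ± 0.19 and -2.96 ± 0.19 (adjusted p = 0.00025 for each). They encode subunits of the cone phosphodiesterase, the enzyme that hydrolyses cyclic GMP in the light response. The green opsin gene opn1mw1 fell by 2.83 ± 0.18, the ultraviolet opsin gene opn1sw1 fell by 2.75 ± 0.18, and gnat2, the cone transducin alpha subunit, fell by 2.82 ± 0.20. The transducin beta subunit gene gnb3b fell by 2.49 ± 0.15 (a second probe, dim in AHRRa, had adjusted p = 0.094), and the cone arrestin gene arr3a fell by 2.35 ± 0.20. Of 14 measured genes of cone phototransduction, 12 fell and 0 rose, both over all genes and adjusted over the list alone, with a median of -2.33. The smallest of these falls was that of gngt2a, a transducin gamma subunit, at -0.76 ± 0.13. The exceptions were six7 and tbx2b, transcription factors of cone subtypes, at 0.16 (adjusted p = 0.76) and 0.09 (adjusted p = 0.76). Camera gave the cone list an adjusted p of 8.5e-18, and adjusted p = 0.31 with an estimated correlation. The study's title names photoreceptor development as affected in these samples, so the photoreceptor lists are not independent evidence of a direction. Opsins are a multigene family, and a probe may also bind the transcript of a relative.

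**Figure D1:**
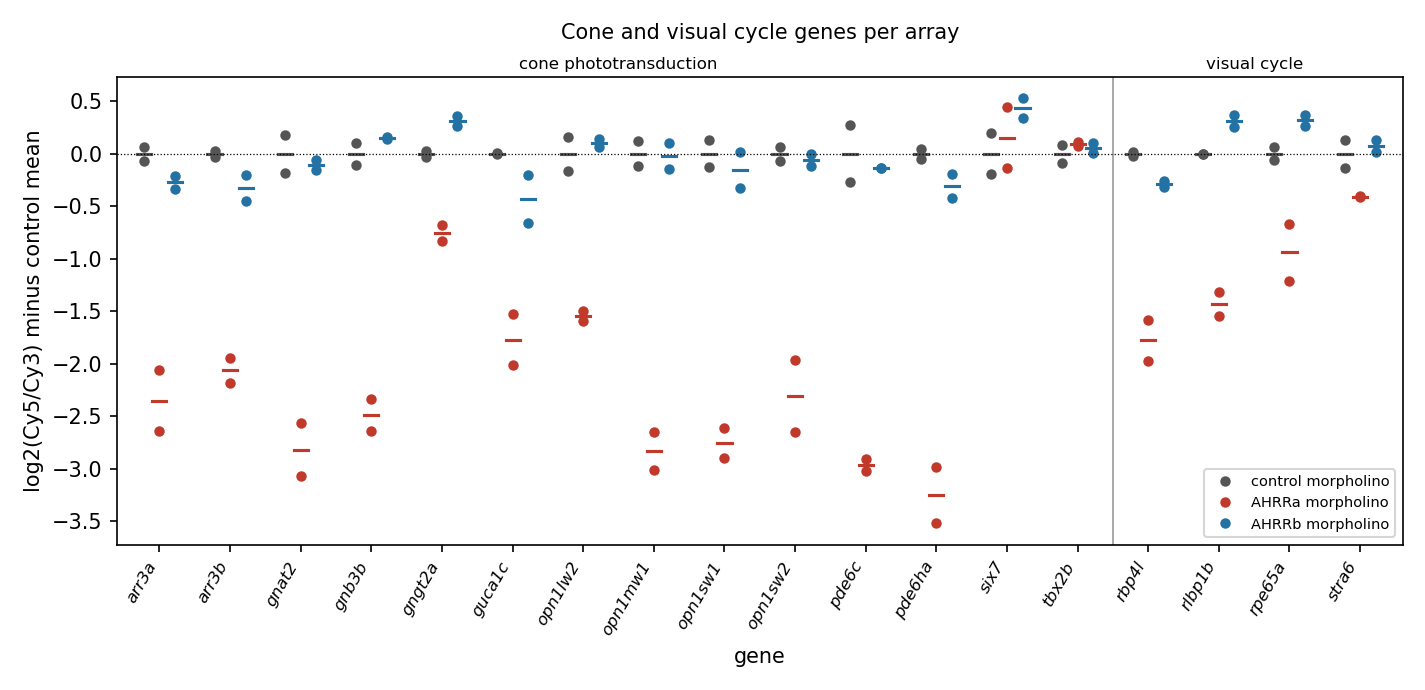
Log2 ratio of Cy5 to Cy3 on each array minus the control mean (vertical axis) for each measured gene of the cone and visual cycle lists (horizontal axis), with a point per array and a short bar for the mean of the 2 arrays of a group. For pde6ha the AHRRa arrays lie at -3.52 and -2.98 and the AHRRb arrays at -0.42 and -0.19, whereas tbx2b lies between -0.09 and 0.12 on all arrays.

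Other photoreceptor and retinal pigment epithelium genes were lower in AHRRa as well. In the visual cycle list 3 of 4 measured genes fell (4 adjusted over the list alone), with a median of -1.18. These were rbp4l, a retinol binding protein gene, at -1.77 ± 0.16, rlbp1b, a retinaldehyde binding protein gene, lower and dim on both AHRRa arrays, and rpe65a, the retinoid isomerase gene, at -0.94 ± 0.19 (adjusted p = 0.044). The retinol receptor gene stra6 had -0.41 (adjusted p = 0.20). Camera gave this list an adjusted p of 2.6e-05, and adjusted p = 0.35 with an estimated correlation. The outer segment disc gene prph2a, in no list, was at least 4.10-fold lower. In the rod list 1 of 4 measured genes fell (1 adjusted over the list alone), the disc gene rom1b, at least 2.51-fold lower, and the list did not pass (median -0.45, adjusted p = 0.24). Of 12 measured photoreceptor and retinal transcription factors 0 passed (1 was lower adjusted over the list alone), with a median of 0.15 and an adjusted p of 0.20. The AHRRa arrays had the fewest probes well above background in Cy5, at 12.6% and 16.3% of probes against 22.9% and 25.3% on the control arrays.

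Of the globin genes, which belong to the other theme that the title names, 2 of 4 measured rose in AHRRa. The embryonic beta globin gene hbbe3 (chromosome 12, 22085579 to 22086654) was at least 8.94-fold higher (adjusted p = 0.00012), being dim on every control and AHRRb array, and the alpha globin gene hbae1.1 rose by 1.09 ± 0.15 (adjusted p = 0.011). The globin genes hbae3 and hbbe2 had 0.56 (adjusted p = 0.066) and -0.36 (adjusted p = 0.28). The list (3 rose and 1 fell adjusted over the list alone) had a median of 0.83 that turned to -0.09 under median centring and to -0.15 with no filter, and a camera adjusted p of 0.00024 (adjusted p = 0.36 with an estimated correlation). Of 11 measured erythroid and heme synthesis genes 0 passed, 0 also adjusted over the list alone (median 0.02, adjusted p = 0.51). In the neutrophil and macrophage list 2 of 5 measured genes rose, the gelatinase gene mmp9, at least 6.32-fold, and cebpb, a myeloid and stress transcription factor gene, by 1.24 ± 0.22 (adjusted p = 0.028). That list did not pass (median 0.12, adjusted p = 0.10), where 2 rose and 1 fell adjusted over the list alone. In AHRRb mmp9, at least 2.71-fold higher (adjusted p = 0.14), and cebpb, at 0.73 (adjusted p = 0.21), lay above control too without passing. Because the title names hematopoiesis, these blood lists are not independent evidence, and globin probes may bind related globin transcripts.

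Digestive organ genes also differed in AHRRa. All 5 measured exocrine pancreas genes fell, also adjusted over the list alone, with a median of -1.47. They included the trypsin gene prss1 at -1.51 ± 0.22, the chymotrypsin gene ctrb.1 at -1.47 ± 0.23, the trypsin family gene prss59.1, lower and dim on both AHRRa arrays, the pancreatic disulfide isomerase gene pdia2, at least 1.99-fold lower, and the amylase gene amy2a, at least 1.67-fold lower. Camera gave the list an adjusted p of 1.4e-06, and adjusted p = 0.34 with an estimated correlation. In the liver and plasma protein list 4 of 20 measured genes rose and 4 fell (8 rose and 6 fell adjusted over the list alone), and the list did not pass (median 0.12, adjusted p = 0.25). The fibrinogen genes fgb, fga and fgg rose by 0.95 ± 0.15, 0.83 and 0.80, and the apolipoprotein gene apoeb rose by 0.82. The vitamin D binding protein gene gc fell by 1.34 ± 0.15, the fatty acid binding protein gene fabp10a fell by 1.27, the transferrin gene tfa fell by 1.11 ± 0.18 (a second probe, dim in AHRRa, had adjusted p = 0.32), and the antithrombin gene serpinc1 was lower and dim on both AHRRa arrays. In AHRRb tfa had -1.16 (adjusted p = 0.066). Among 3 measured intestine genes, too few to test, the microvillus gene vil1 was at least 2.09-fold lower. The antifreeze protein family gene afp4, in no list, rose by 1.11 ± 0.13.

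The cyclin gene ccng1 rose by 1.15 ± 0.13 in AHRRa (adjusted p = 0.0042). In the stress list 1 of 24 measured genes rose, the immediate early gene junba, by 1.28 ± 0.18 (1 rose and 1 fell adjusted over the list alone), and the list did not pass (median -0.05, mean 0.06 and camera direction higher, adjusted p = 0.61). In AHRRb junba had 0.82 (adjusted p = 0.11).

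**Figure D2:**
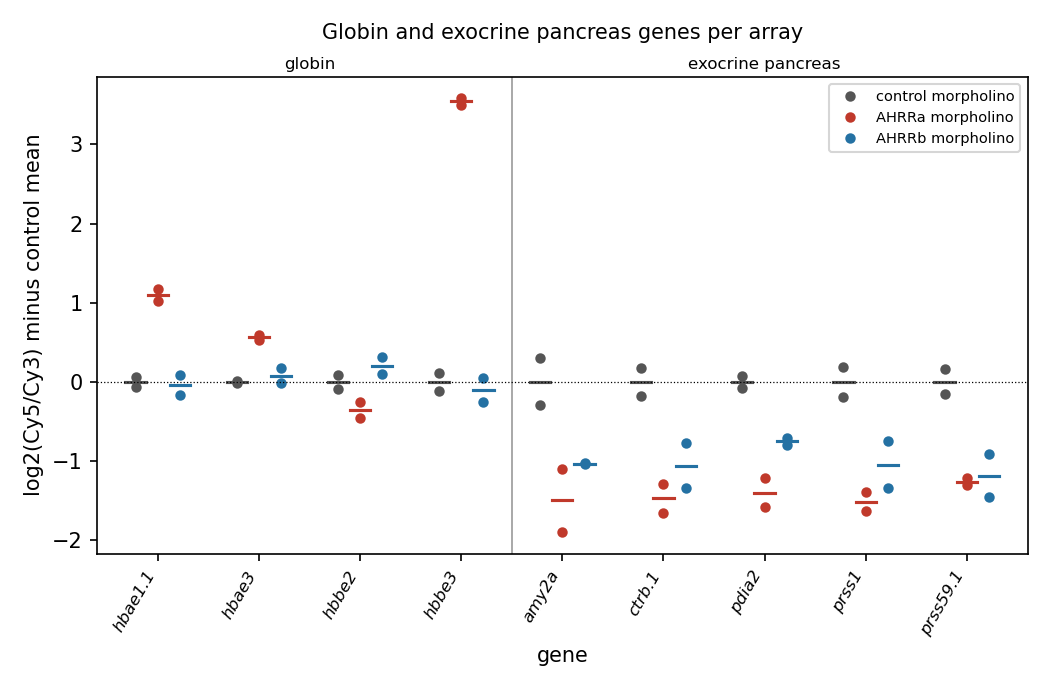
Log2 ratio of Cy5 to Cy3 on each array minus the control mean (vertical axis) for each measured globin and exocrine pancreas gene (horizontal axis), with a point per array and a short bar for the mean of the 2 arrays of a group. The hbbe3 points of AHRRa lie at 3.58 and 3.50 (control and AHRRb arrays were dim for it) and prss1 lies at -1.64 and -1.39 in AHRRa and at -1.34 and -0.75 in AHRRb.

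Among neuron genes 3 of 17 measured fell in AHRRa (6 adjusted over the list alone), with a median of -0.29. These were calb2a, the calretinin gene, at -0.77 ± 0.13, pvalb7, a parvalbumin gene, at least 1.36-fold lower, and gad1b, the GABA synthesis gene, lower and dim on both AHRRa arrays. Camera gave an adjusted p of 0.00051, which was lost without the first AHRRa array (adjusted p = 0.31 with an estimated correlation). The lens list had a median of 0.51 that turned to -0.26 under median centring, with 1 of 18 measured genes past the test (6 adjusted over the list alone), lim2.3, a lens membrane gene that was dim in both groups. Its camera adjusted p was 5.9e-08, and adjusted p = 0.44 with an estimated correlation. Crystallins, like keratins, are multigene families whose probes may bind related transcripts. In the circadian list bhlhe40, a clock repressor gene, fell by 0.85 ± 0.16 (a second probe, dim in AHRRa, had adjusted p = 0.80), as 1 of 7 measured genes (4 adjusted over the list alone), with a list median of -0.34 and an adjusted p of 0.014 that was lost without the second AHRRa array. The cell cycle list passed with a median of 0.10 over the 17 of 18 measured genes that had a value on every array (0.16 with mcm7, the other) and 0 past the test, 0 also adjusted over the list alone (adjusted p = 0.011, lost without the second AHRRa array), and its median was -0.59 under median centring and -0.09 with the processed signals. For both lists camera gave adjusted p = 0.44 with an estimated correlation. In the epidermis list 2 of 16 measured genes rose and 3 fell (2 and 4 adjusted over the list alone), and the list did not pass (median -0.18, adjusted p = 0.42). The keratin gene krt17 rose by 0.83 ± 0.16, with -0.05 under median centring, and the claudin gene cldnb rose by 0.70. The keratin genes cyt1, krt15 and krt97 fell by 0.72, 0.80 and 0.61. The cathepsin gene ctslb, a hatching gland marker, was lower and dim on both AHRRa arrays, as 1 of 6 measured genes of a list that did not pass (median 0.10, mean -0.14, camera direction higher, adjusted p = 0.79; 1 rose and 1 fell adjusted over the list alone). Second probes of fga, ctslb, krt97 and lim2.3 had the same sign and did not pass (adjusted p = 0.066, 0.065, 0.13 and 0.17), nor did 2 others of pvalb7 (0.079 and 0.24) and 1 of 2 others of fgb (0.19).

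The remaining lists did not pass in AHRRa, and 0 of their genes did. These were skeletal muscle (27 measured, median 0.03, mean -0.03, adjusted p = 0.51), heart muscle (5, median 0.01, adjusted p = 0.42), glia and myelin (8, median -0.12, adjusted p = 0.51) and cartilage and bone (11, median -0.06, adjusted p = 0.74). Camera put the cartilage list on the higher side although its median and mean were below 0. Adjusted over the list alone, 2 glia genes were lower and 0 genes of the other lists passed. Of the lists too small to test, the blood stem cell, endocrine and pigment cell lists had 0 genes past the test, and 0 vascular and 0 interferon genes were measured.

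In AHRRa against control 155 of 5006 probes passed the limma test, 40 higher and 115 lower, for 107 assigned symbols (24 higher and 83 lower), where 891 passed an unadjusted p of 0.05 and 250.3 would by chance. Of the 155, 55 were dim on both AHRRa arrays but not on both control arrays. Among the 2591 probes well above background in both channels on all arrays, 105 passed, 37 higher and 68 lower. The shared spread is narrower than that of AHRRa, whose replicates differed with a standard deviation of 0.42 against 0.18 for control and for AHRRb. Standard errors and p-values of both comparisons with AHRRa are therefore too small on average. With array weights, added after the data were seen, 115 probes passed. The AHRRa and control arrays did not overlap for 45.9% of tested probes, where chance gives 33.3% if the arrays of both groups vary alike. With the wider spread of AHRRa chance gives more, so that reference is too low. The count was 13 without the first control array, 21 without the second, 903 and 1265 without the first and the second AHRRa array, and 42 without either AHRRb array or with only these 2 groups in the model. Of the 39 genes past the test that the naming rule picked, hbbe3, pde6ha, pde6c, opn1mw1, gnat2, opn1sw1, gnb3b, arr3a and prph2a also passed under every alternative that measured them. Each of the others lost its call without a control array, which for rbp4l was the first only. Median centring in place of loess moved the median of all tested probes to -0.79 and the count to 2016 probes, 3 higher and 2013 lower, and the processed signals moved it to -0.31 with 35 higher and 699 lower. Relative to the shift under median centring, the medians were 0.53 for the lens list, 0.69 for globins and 0.19 for the cell cycle.

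AHRRb against control asked the same of the second repressor, and no single gene passed the main test. The lowest adjusted p, 0.0503, was shared by abcf2a, a gene of an ATP-binding protein of the ABCF family, at -1.64 ± 0.17, fkbp5, a glucocorticoid-induced chaperone gene, at -1.28 ± 0.15, and ctrb.3, a chymotrypsin gene, lower and dim on both AHRRb arrays. The next genes below control were the chymotrypsin gene ctrb.2, afp4 (-0.96), the chaperone gene hspa4a (-1.02), the Mediator kinase gene cdk8 (at least 1.89-fold lower) and dnajc21 (-0.97), each at an adjusted p of 0.0656. Above control lay txnipb, a thioredoxin-interacting protein gene, at 1.04 ± 0.15 (adjusted p = 0.0656), the cytokine signalling suppressor gene socs3b at 0.99, krt17 at 0.87, the mitochondrial carrier gene slc25a36a at 0.76, the glycogen regulator gene ppp1r3ca at 1.06, ndrg1b (at least 2.53-fold), ypel3 at 0.86 and lim2.3 (dim on both control arrays), with adjusted p up to 0.10.

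As groups, 8 of 22 lists passed camera in AHRRb with 0 members past the test, and all 8 had adjusted p = 0.36 with an estimated correlation. Lens genes lay above control, with a median of 0.77, 18 of 18 measured genes above 0 (adjusted p = 5.7e-13; 15 higher adjusted over the list alone). Liver and plasma protein genes lay below, with a median of -0.42, 19 of 20 below 0 (adjusted p = 2.05e-10; 9 lower adjusted over the list alone). The 5 exocrine pancreas genes had a median of -1.05 (adjusted p = 7.4e-07; 5 lower adjusted over the list alone), with prss1 at -1.05 and prss59.1 at -1.19. Cartilage and bone genes had a median of -0.32, 11 of 11 below 0 (adjusted p = 0.0028; 1 lower adjusted over the list alone). Retinal transcription factors had 0.30, 11 of 12 above 0 (adjusted p = 0.0044; 0 adjusted over the list alone), circadian genes 0.20 (adjusted p = 0.012; 2 higher adjusted over the list alone) and skeletal muscle genes 0.16, 23 of 27 above 0 (adjusted p = 0.018; 0 adjusted over the list alone). Stress genes had -0.13 (adjusted p = 0.0499; 1 higher and 4 lower adjusted over the list alone). The skeletal muscle and the stress call were each lost without the first control array and without the second AHRRb array. Both calls were also lost with Cy5 only and with no filter. That of skeletal muscle was lost with the processed signals and the deposited series table too, and that of stress with scale normalization and the stricter filter. The circadian call was lost under median centring, with Cy5 only and with no filter. Cy5 only also lost the cartilage and the retinal factor call, and the stricter filter lost the latter. The retinal factor list is among those the title concerns and is not independent evidence.

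Cone genes had a median of -0.08 in AHRRb (adjusted p = 0.76; 0 of 14 adjusted over the list alone), and globins 0.02 (adjusted p = 0.85). The other medians of lists that did not pass in AHRRb were 0.19 for the visual cycle (adjusted p = 0.58), 0.05 for rods (adjusted p = 0.94), -0.12 for the cell cycle (adjusted p = 0.072), 0.11 for neurons (adjusted p = 0.094), 0.12 for epidermis (adjusted p = 0.13), 0.06 for glia (adjusted p = 0.68), -0.19 for heart (adjusted p = 0.77), -0.05 for the hatching gland (adjusted p = 0.34) and 0.00 for erythroid genes (adjusted p = 0.94), whose camera direction was lower. Adjusted over the list alone, 4 epidermis genes were higher and 2 lower, 1 hatching gland gene was lower and 0 of the others named here passed. The neutrophil and macrophage list had a median of -0.06, a mean of 0.20 and an adjusted p of 0.93, with 2 genes higher and 1 lower adjusted over the list alone. Median, mean and test of the AHR pathway list differed too, with a median of 0.02, a mean of -0.12 and a camera direction below control.

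**Figure D3:**
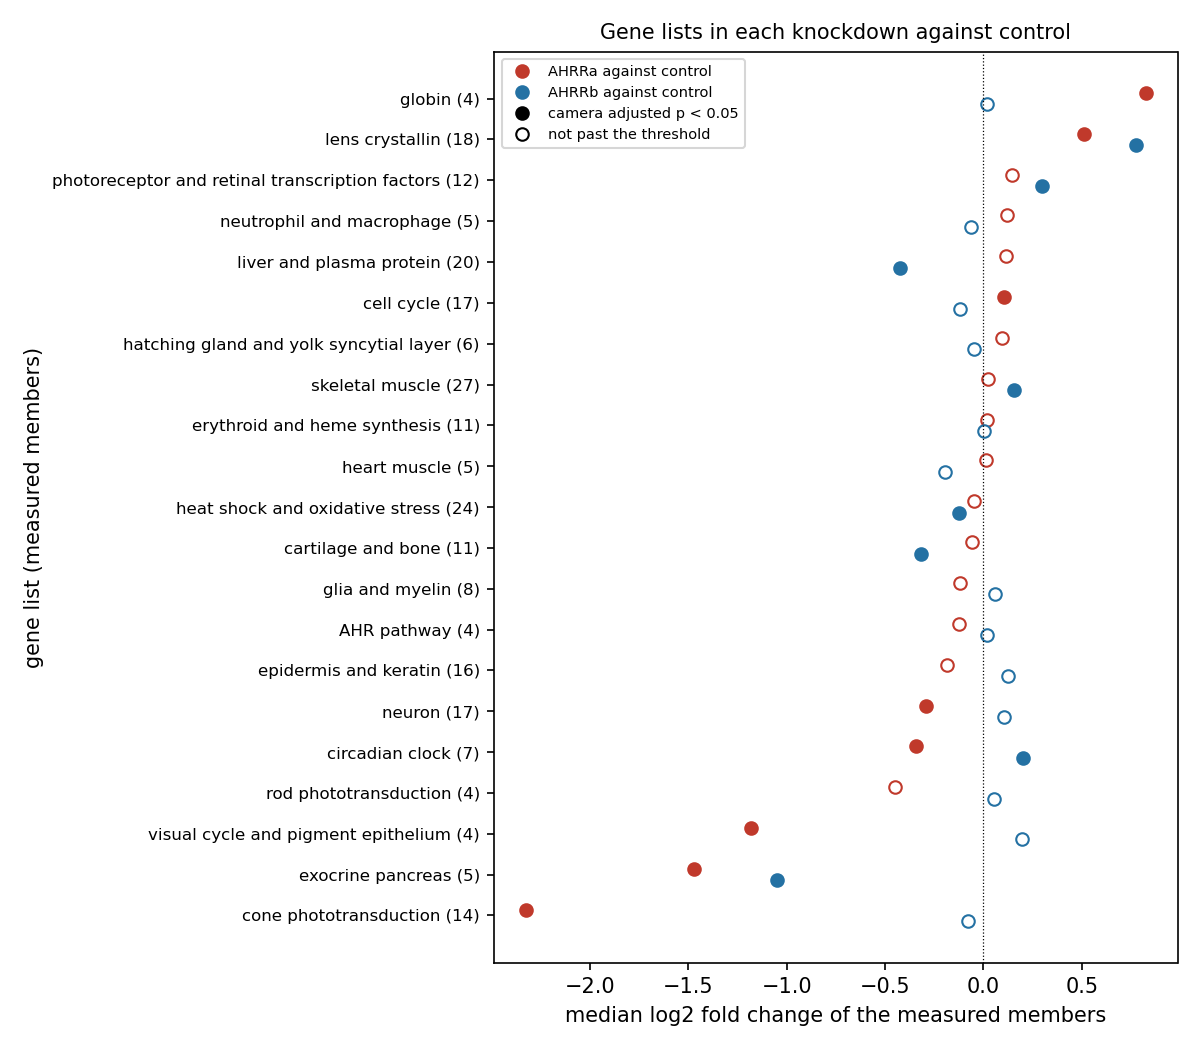
Median log2 change of the measured genes of each list shown (horizontal axis) against control, for AHRRa (red) and AHRRb (blue), with filled points for a camera adjusted p under 0.05 and the number of measured genes beside each list name. The cone list lies at -2.33 in AHRRa and -0.08 in AHRRb, the exocrine pancreas list at -1.47 and -1.05, and the lens list at 0.51 and 0.77. Under median centring the AHRRa medians of the lens, globin and cell cycle lists turn negative, to -0.26, -0.09 and -0.59.

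With limma 0 of 5006 probes passed in AHRRb against control, where 626 passed an unadjusted p of 0.05 against 250.3 by chance and 64 passed at an adjusted p of 0.1. The AHRRb and control arrays did not overlap for 56.6% of tested probes, where chance gives 33.3%. This count of 0 rests on the spread shared with the AHRRa arrays. With only the AHRRb and control arrays in the model 594 probes passed, 227 higher and 367 lower. Leaving out either AHRRa array gave the same result by construction, as a lone AHRRa array adds nothing to the spread. Array weights, added after the data were seen, gave 573, a replicate block 123, the processed signals 75 and no background correction 42.

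AHRRa against AHRRb compared both knockdowns within one slide. The same cone genes were lowest in AHRRa, with pde6ha at -2.94 ± 0.19, pde6c at -2.82 ± 0.19, opn1mw1 at -2.81 ± 0.18, gnat2 at -2.71 ± 0.20 and gnb3b at -2.64 ± 0.15. Of 14 measured cone genes 12 were lower, 12 also adjusted over the list alone (median -2.16, adjusted p = 9.5e-15, and adjusted p = 0.24 with an estimated correlation). In the visual cycle list 3 of 4 were lower, 4 adjusted over the list alone (median -1.37, adjusted p = 0.00011, and adjusted p = 0.32 with an estimated correlation), and in the rod list rom1b was at least 2.47-fold lower (list adjusted p = 0.30; 2 lower adjusted over the list alone). The retinal factor gene six3b was at least 1.43-fold lower (list adjusted p = 0.35; 2 lower adjusted over the list alone). The largest rises were those of hbbe3, at least 8.69-fold higher (adjusted p = 9.5e-05), afp4 at 2.07 ± 0.13, the lysosomal protease gene ctsla at 1.89 ± 0.19, the collagen chaperone gene serpinh1b at 1.37 ± 0.15 and fgb at 1.34 ± 0.15. The globin list had 2 of 4 measured genes higher, with hbae1.1 at 1.13 (3 higher and 1 lower adjusted over the list alone), and a median of 0.81 (adjusted p = 0.0035, and adjusted p = 0.32 with an estimated correlation) that was -0.27 under median centring.

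Liver genes differed between the knockdowns, with 9 of 20 measured genes higher in AHRRa and 2 lower (12 and 3 adjusted over the list alone), and a median of 0.82 (adjusted p = 1.2e-06, and adjusted p = 0.32 with an estimated correlation) that was -0.06 under median centring. Examples were fga at 1.15, the vitronectin gene vtnb at 1.08 and gc at -1.37. All 17 measured neuron genes lay below 0, with 6 past the test (11 adjusted over the list alone) and a median of -0.51 (adjusted p = 6.8e-05, and adjusted p = 0.24 with an estimated correlation), among them the synaptotagmin gene syt1a at -0.88, pvalb7, at least 1.42-fold lower, calb2a at -0.75, gad1b, at least 1.34-fold lower, and the synaptic vesicle genes snap25b and sypb at -0.71 and -0.64. The 7 circadian genes lay below 0 as well, with 4 past the test (6 adjusted over the list alone) and a median of -0.68 (adjusted p = 0.00017, and adjusted p = 0.32 with an estimated correlation), among them bhlhe40 at -1.05, nr1d2b at -0.86, ciarta at -0.68 and nr1d1, at least 1.53-fold lower. In the cell cycle list 16 of the 17 genes tested lay above 0 and the replication helicase gene mcm5 was higher by 0.81 (1 also adjusted over the list alone), with a list median of 0.24 (0.30 with mcm7, adjusted p = 0.00019, and adjusted p = 0.32 with an estimated correlation), but the signs of mcm5 and of the list turned under median centring, to -0.06 and -0.58.

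A further 3 lists passed with signs that turned under median centring. They were cartilage (median 0.26, -0.75 under that setting, adjusted p = 0.0084, a call lost without the first AHRRa array), neutrophil and macrophage (0.42 and -0.43, adjusted p = 0.032) and stress (0.14 and -0.77, adjusted p = 0.039), the last 2 of which were also lost without the first AHRRa and without the second AHRRb array. With an estimated correlation the adjusted p of these lists was 0.40, 0.32 and 0.33. In cartilage the hypertrophic collagen gene col10a1a was higher by 0.92 (-0.01 under median centring; 4 higher adjusted over the list alone), and in the stress list the endoplasmic reticulum chaperone gene hspa5 was higher by 0.71 (-0.35 under median centring; 5 higher adjusted over the list alone). Keratin genes cyt1, krt15 and krt91 were at -1.19, -1.11 and -0.67, as 3 of 16 in an epidermis list that did not pass (adjusted p = 0.085; 1 higher and 6 lower adjusted over the list alone). The cyclin gene ccng1 was higher by 1.06. In lists that did not pass, crybgx of the lens was at -1.04 (adjusted p = 0.27 for the list) and the muscle actin gene acta1a at -0.74 (0.27). In the hatching gland list, which did not pass either (0.35), the apolipoprotein gene apoa4b.1, also of the intestine list, was at 1.29, and ctslb was lower and dim on both AHRRa arrays. The lists of exocrine pancreas (adjusted p = 0.14), heart (0.27), glia (0.27), erythroid genes (0.44) and the AHR pathway (0.97; median -0.07, camera direction higher) had 0 genes past the test. Adjusted over the list alone, 1 gene was lower in each of the lens and exocrine lists, 2 were lower in the glia list, 1 was higher and 1 lower in the erythroid list, 2 were higher and 1 lower in the hatching gland list, 1 was higher in the neutrophil and macrophage list, and 0 passed in the muscle, heart and AHR lists. In lists too small to test, vil1 was at least 1.69-fold lower and the melanin synthesis gene tyrp1b at -0.63. Second probes of acta1a, bhlhe40, vtnb, krt91, col10a1a and mcm5 had the same sign and did not pass (adjusted p = 0.78, 0.20, 0.10, 0.12, 0.070 and 0.081), nor did 1 of 2 others of pvalb7 (0.11).

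For AHRRa against AHRRb 332 of 5006 probes passed, 110 higher and 222 lower in AHRRa, for 228 assigned symbols, with 1287 at an unadjusted p of 0.05. Of the 332, 110 were dim on both AHRRa arrays but not on both AHRRb arrays, and the AHRRa arrays had fewer probes well above background. Among the 2591 probes well above background in both channels on all arrays, 231 passed, 116 higher and 115 lower. The excess of lower probes in AHRRa therefore depended on the filter. The AHRRa and AHRRb arrays did not overlap for 51.9% of tested probes, where chance gives 33.3% if both groups vary alike and more with the wider spread of AHRRa. The count was 16 and 19 without the first and the second AHRRb array, 79 without either control array, and 1588 and 1494 without the first and the second AHRRa array. Of the 42 genes that the naming rule picked, hbbe3, afp4, pde6ha, pde6c, opn1mw1, gnat2, gnb3b and rlbp1b passed under every alternative that measured them, and each other gene lost its call without an AHRRb array, which for gc was the second only. Median centring moved the median of all tested probes to -0.88, with 5 probes higher and 3050 lower, and the processed signals moved it to -0.30, with 86 higher and 1010 lower. Relative to the shift under median centring the medians were 0.83 for liver, 0.62 for globins, 0.31 for the cell cycle, 0.45 for neutrophils and macrophages and 0.13 for cartilage.

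Both comparisons with control used the same 2 control arrays, which gives their changes a shared part. Their log2 changes correlated across probes at r = 0.25. Unchanged groups against 2 shared controls, all simulated with one spread in every group, gave 0.50 on average, between 0.46 and 0.55 in 100 simulations. Equal spread fixes that correlation near 0.50. Real replicates differed with a standard deviation of 0.42 in AHRRa against 0.18 in control and in AHRRb, so the simulated values are only a rough reference. The covariance was 0.0244 against 0.0151 in those simulations, between 0.0136 and 0.0173, a difference to which the slide also contributes if it shifts both knockdowns. Since AHRRb had 0 calls, 0 probes passed in both. At an unadjusted p of 0.05, 145 probes passed in both with the same direction, 43 higher and 102 lower, where independent comparisons would give 11.5 and 50.4 and the simulated groups gave 57.1 in all, between 36 and 79. The simulated groups held no change, and chance gives 250.3 probes at that p in a comparison, against 891 and 626 here. They are therefore no reference for the overlap of 2 groups with many such probes. The 2 control arrays were not split between the comparisons, so part of the excess over independent comparisons may come from the shared arrays. The slide may contribute to it too.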

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

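Every test weighed here was chosen after the result it bears on was seen, except that of a single deviant control array, which was written down before its value was known.

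The test of the difference between AHRRa and AHRRb set apart 332 probes, 10 gene lists and 32 of the 53 genes named in the comparisons with control, 8 higher and 24 lower in AHRRa. With an estimated correlation 0 of these lists passed, and their adjusted p lay between 0.24 and 0.40.

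The first pattern was the lower level of cone and visual cycle genes in AHRRa. A slide or scan effect was argued against by AHRRb arrays on the same slide, from which the AHRRa cone median differed by -2.16. Weak Cy5 signal on the AHRRa arrays as the whole cause was argued against by random lists matched on Cy5 level, of which 0% had so low a median (permutation p over genes = 0.0001, the smallest that 10000 draws can give), the lowest being -0.44 against -2.33. Less eye tissue as a whole was argued against by the lens list, whose median differed by -0.15 between the knockdowns on one slide, against -2.16 for cone genes. In AHRRa against control the lens median was 0.51, which the slide could have shifted. It turned to -0.26 (0.53 relative to all probes) under median centring. Loss of the retina as a whole was weighed with retinal transcription factor genes, though some are also expressed in brain. The 8 well above background on at least 1 array of every group had a median of -0.031 between the knockdowns and a lowest value of -0.69. That filter leaves out genes that fell to background in AHRRa, so the 8 alone cannot decide. Over all 12 measured the median was -0.13 and the lowest value -0.86, against -2.16 for cone genes. This argues against an equal fall of these genes as a set, but 4 were dim in AHRRa and their falls are not bounded. Between the knockdowns 4 of 4 visual cycle genes (median -1.37) and 17 of 17 neuron genes (median -0.51) lay below 0 as well. The fall was thus not confined to cone genes, and a partial loss of other retinal cells was not tested. A change in cone and visual cycle gene expression after AHRRa knockdown is the biological candidate. Loss of cone cells alone, a delay in eye development and an effect of this morpholino on other transcripts stay open as untested.

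The second pattern was the shift of lens and exocrine pancreas genes in the same direction in both knockdowns against control. It follows the split of the arrays into slides, and between the knockdowns on one slide the lens median differed by -0.15 and the exocrine median by -0.46, with 5 of 5 exocrine genes below 0, neither past the test (adjusted p = 0.27 and 0.14), so a slide or scan effect and an effect shared by both knockdowns cannot be told apart. One deviant control array as the cause of the lens shift was argued against by AHRRb medians of at least 0.66 without either control array, against 0.77 with both. The genes mmp9, cebpb, junba and tfa also moved the same way in both knockdowns against control. They did not pass between the knockdowns (adjusted p = 0.083, 0.20, 0.16 and 0.79), though a second tfa probe did (0.039), so the same limit applies to them. Lens genes also varied between replicate arrays, given here relative to the control mean. Most were higher on the first array of a group, such as lim2.4 (0.32 and -0.32 in control) and cryba1b (1.40 and 0.67 in AHRRb). In control and AHRRb exocrine genes varied the other way, such as prss1 (-0.19 and 0.19, and -1.34 and -0.75). A source of variation other than slide and knockdown was therefore not excluded for the lens and exocrine lists.

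Lists that differed between the knockdowns by that test had these median log2 differences, AHRRa minus AHRRb. They were -2.16 for cone phototransduction, 0.82 for liver and plasma protein, -0.51 for neurons, -1.37 for the visual cycle, -0.68 for the circadian clock, 0.24 for the cell cycle, 0.81 for globins, 0.26 for cartilage and bone, 0.42 for neutrophils and macrophages and 0.14 for stress genes, and under median centring the liver, cell cycle, globin, cartilage, neutrophil and stress medians turned negative.

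Photoreceptor and visual cycle genes that differed were pde6ha (-2.94), pde6c (-2.82), opn1mw1 (-2.81), gnat2 (-2.71), gnb3b (-2.64), opn1sw1 (-2.60), prph2a (-2.39), arr3a (-2.08), rlbp1b (-1.74), rom1b (-1.64), rbp4l (-1.49) and rpe65a (-1.26). Other genes lower in AHRRa were ctslb (-1.91), gc (-1.37), cyt1 (-1.19), krt15 (-1.11), vil1 (-1.10), bhlhe40 (-1.05), ppp1r3ca (-0.96), pvalb7 (-0.88), txnipb (-0.87), gad1b (-0.83), slc25a36a (-0.76) and calb2a (-0.75). Genes higher in AHRRa were dnajc21 (0.61), abcf2a (0.79), cdk8 (0.96), ccng1 (1.06), hbae1.1 (1.13), fgb (1.34), afp4 (2.07) and hbbe3 (3.65). For genes that were dim in one group these fitted differences are no bound on the fold.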

How the results depend on the processing

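Of the alternatives, only array weights were chosen after the data were seen. The counts of called probes were the least stable results, and the cause was not tested except where fewer arrays, probes or groups entered by construction. The cone, lens, exocrine pancreas and visual cycle lists kept their camera calls in AHRRa under every alternative that refitted them at the preset correlation (19, 19, 18 and 18), as did the lens, liver and exocrine lists in AHRRb. With an estimated correlation each of these calls was lost, the lowest adjusted p being 0.31 in AHRRa and 0.36 in AHRRb. Over the named genes, 1569 values under an alternative kept their side of the threshold and their sign, 376 no longer passed, 127 newly passed and 8 turned sign. Aquantile normalization leaves log ratios as they are, so it tested nothing, yet its 101 values and its list calls are among those counted as kept. A lone array in the group outside a comparison adds nothing to the spread. Such fits therefore repeat the model of only the 2 groups compared. A slide term could not be fitted.

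In the order AHRRa against control, AHRRb against control, AHRRa against AHRRb, and called in both against control with one direction, the main counts were 155, 0, 332 and 0. They were 734, 75, 1096 and 30 with the processed signals, 315, 42, 522 and 9 with no background correction, and 2016, 6, 3055 and 3 with median centring. A replicate block gave 290, 123, 608 and 39, and a threshold of 0.1 gave 291, 64, 702 and 14. With Cy5 only the counts were 259, 10, 253 and 5. With no filter AHRRa against control gave 19 and AHRRa against AHRRb 22. With only the 2 groups compared the first 3 counts were 42, 594 and 79. Array weights gave 573 for AHRRb, 187 between knockdowns and 28 in both. For AHRRb and for both, the stricter filter gave 16 and 3, the mean over the probes of a gene 5 and 3, and trend with robust 1 and 1.

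Leaving out 1 array, where the lone array is assumed to vary like the other groups, gave 13 to 1265 probes for AHRRa, 0 to 594 for AHRRb, 16 to 1588 between knockdowns and 0 to 187 in both. The correlation of the changes, 0.25, was 0.41 with Cy5 only, 0.47 with no filter, and 0.15 to 0.33 with 1 array left out. Lists past the threshold, 9, 8 and 10, were 0, 0 and 0 with an estimated correlation and 5, 0 and 10 with fry. With Cy5 only AHRRb had 3. With 1 array left out they were 7 to 9, 6 to 9, and 8 to 11.

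The sign of ahr2 in AHRRa turned to 0.11 with no background correction, 0.16 with Cy5 only, and 0.04 and 0.19 without the first control and the second AHRRa array, in a range of -0.22 to 0.19 with 1 array left out. Under median centring krt17 in AHRRa turned to -0.046, and between the knockdowns col10a1a turned to -0.0078, mcm5 to -0.055 and hspa5 to -0.35. The replicate numbers could pair arrays, but deviations from the group means correlated across probes at 0.36, 0.18 and 0.36 between groups, and 2 numbers cannot establish a pairing, so the block counts (123 for AHRRb) have no firmer standing than the main ones. The AHRRa arrays had the fewest probes well above background in Cy5, 12.6% and 16.3%.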

Other observations

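In AHRRb embryos genes of ribosome biogenesis, the nucleolar assembly of ribosomes, lay below control. The box C/D snoRNP methylase gene fbl was at -0.70 ± 0.13 (adjusted p = 0.076), the ribosome synthesis regulator gene rrs1 at -0.97 ± 0.21 (adjusted p = 0.11) and the snoRNP scaffold gene nop56 at -0.76 ± 0.22 (adjusted p = 0.20). The nucleophosmin gene npm1a was at -0.86 ± 0.14 (adjusted p = 0.068). None passed the test.

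The hypothesis that the class is lower in AHRRb arose from nop58, npm1a and dnajc21 after their values were seen. A list of 58 ribosome biogenesis genes was then written, and its 29 measured genes other than those 3 were tested, with the prediction fixed before their values were known. In AHRRb against control 28 of the 29 lay below 0, with a median of -0.48 and 0 past the threshold. Of 10000 random lists matched on mean intensity 0% had so low a median (permutation p over genes = 0.0001, the smallest they can give), and their lowest was -0.20. In AHRRa against control the median was -0.17, and 1.72% of random lists were as low. Between the knockdowns on one slide the AHRRa median was higher by 0.36, with 25 of 29 above 0, 1 past the threshold and 0% of random lists as high. These values are consistent with lower expression of the class in AHRRb embryos, but genes of one class vary together, so random lists understate the spread. In the comparison with control the slide could have contributed, whereas the within-slide difference may come from either knockdown.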
